A study of Mus musculus with 4 samples.

How the data were processed

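RNA of mouse HT22 cells was measured by RNA-seq in 4 libraries, 2 from a control line and 2 from a line made to overexpress MEIS2. Per the labels' protocols, total RNA was taken up in TRIzol, its integrity was checked on a Bioanalyzer, transcripts with poly(A) tails were selected on oligo(dT) beads and fragmented with divalent cations, and libraries were made with a New England Biolabs protocol. Selection on poly(A) tails leaves little of transcripts without a tail in a library, and makes the coverage of long transcripts depend on how intact the RNA was. The values are whole-number read counts per gene in 1 deposited table with 1 column per library, and per the file headers each row also gives an Ensembl gene ID, a symbol, a chromosome, a start, an end, a strand and a gene length in bases. DESeq2 is named, with no version, per the submitters' processing notes. The aligner, the counting program, its treatment of strand and of reads that match several genes, the annotation release and the genome build are not given in the sources used here. Of 52073 gene IDs shared with GENCODE M21 on GRCm38, 1472 had the same start and end, so positions are printed as the file gives them, with no build.

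Total counts were 16903967 and 16445575 in control replicates 1 and 2, and 15705070 and 15014017 in MEIS2 replicates 1 and 2. A count of 3, used as a floor for detection, was worth between 0.177 and 0.2 CPM, and such floors cover counting error only. The count tables of libraries from 1 line differed by far more than sampling noise (chi-square per degree of freedom 36.3 for the controls and 95.2 for the MEIS2 libraries). They were therefore not summed, and each library was counted as 1 replicate. Separate libraries of 1 culture could differ in this way too, so the values do not show separate cultures. Every row named a gene, and no column of sample values was left unused.

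Counts were tested as deposited in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr with the group, libraries were scaled by TMM, and the group term alone was tested with the quasi-likelihood F test. Adjusted p-values are Benjamini-Hochberg values over the 12802 genes tested, with a threshold of 0.05. The standard error (SE) of a log2 fold change is its size divided by the square root of F. CPM is a count relative to the total of its library. Levels are TMM-scaled CPM, given as mean ± SD over the 2 libraries of a line. Deviations of a library from the mean of a gene use log2 CPM with a prior count of 2.

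A set of 36 gene lists was fixed before the data were examined, as were the tests, the rule for named genes and all alternatives but the trend offset below. List entries were matched by symbol, 17 of them through an older symbol, and 2 entries matched no gene of the table. Lists with at least 5 tested members, 31 of them, were compared with all other tested genes by camera in limma 3.58.1 with a preset correlation of 0.01 between genes, and p-values were adjusted over the lists. The same lists were tested with a correlation estimated for each list and with fry, which tests whether the genes of a list move on balance in 1 direction or, in its mixed form, in either direction, and compares them with no other genes. Lists that share members are not independent of each other. With an estimated correlation, camera rests on the 2 residual degrees of freedom of the libraries, so adjusted over 31 lists it could call little. The estimated correlation was -0.011, 0.015 and 0.014 for the axon guidance, Notch and Hippo lists, near the preset 0.01. For these 3 lists, a call lost in that test is no sign of correlation between genes. Fry measures spread on the same 2 residual degrees of freedom, so it too could call little.

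The rule for named genes takes Meis2, up to 10 genes with the largest rise and 10 with the largest fall among those past the threshold with a mean CPM of at least 5 and no overlap between the lines, the 5 lowest p-values in each direction, up to 2 genes of each list past the threshold in each direction, and the most abundant member of each list of another cell type. Unnamed gene models and pseudogenes are left out of the largest changes and lowest p-values. Since 1 gene passed, most genes named for a list were chosen after their values were seen, and the text gives their values without a call. Values of some single list members are not reported here.

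GC content was that of the longest GENCODE M21 transcript with the same gene ID and was found for 98.9% of the tested genes. Near-identical copies of Meis2, Sumo2 and Rpl21 were sought among those transcripts with BLAST+ 2.17.0, at 90% identity or more over at least 150 bases that cover at least 50% of the copy.

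The alternatives tried were DESeq2 size factors, library size alone and upper quartile scaling, no filter on low counts, a filter at 5 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, a threshold of 0.01, a test against a fold change of 1.5, the replicate number as a block, and leaving out each library. After the data were seen, an offset was added that removes each library's loess trend (span 0.3) on gene length and GC content, with and without the block. With 1 library of a line left out, the remaining library of that line was assumed to vary like those of the other line. Such fits, and those with the block, have fewer residual degrees of freedom than the 2 of the main fit.

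The steps were tested on simulated data. For control against MEIS2 overexpression with the dispersion seen here (12580 genes tested), the test recovered 7.5% of genes changed 2-fold, 75% of those changed 4-fold and 97.5% of those changed 16-fold, and called 9 unchanged genes. With no gene changed, 0 of 12578 genes were called. These simulated genes were drawn independently at the fitted dispersion trend, without the length and GC trends between the real libraries. The recovered shares therefore need not hold for the real data, where Sumo2, at a fitted 6.71-fold, and Crebbp, at 4.06-fold, were not called. A list of 30 genes raised 1.5-fold reached an adjusted p of 3.44e-07 by camera, and 0 of the other simulated lists were called. The genes of these lists were drawn independently, so false calls of lists whose genes move together were not tested. In simulated libraries with a length trend, the offset lowered the largest rank correlation with gene length from 0.658 to 0.00443.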

Results

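HT22 is an immortalised line of mouse hippocampal neurons. MEIS2 is a homeodomain transcription factor of the TALE class that binds DNA together with PBX and HOX proteins. A line overexpressing MEIS2 was compared with a control line, to find what the factor does to the transcriptome of these cells. Such a comparison cannot tell an effect of MEIS2 from another difference between the lines. Poly(A)-selected RNA was counted per gene in 2 libraries of each line, with total counts from 15014017 to 16903967. Of 56748 genes in the table, 35172 had 0 counts in all 4 libraries and 12802 had enough counts to be tested. The labels do not say whether the libraries of a line came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

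Meis2 itself was 18.7-fold higher in the overexpressing line. Its normalised level was 17.8 ± 2.59 CPM in the controls and 332.1 ± 0.0790 CPM in the MEIS2 libraries (SD, n = 2 each), from 245 and 319 counts against 5182 and 5571. The log2 fold change was 4.22 (SE 0.34) with an adjusted p of 6.41e-05 in edgeR's quasi-likelihood test, and both MEIS2 libraries lay above both controls. The gene (ENSMUSG00000027210) lies on the minus strand of chromosome 2 from 115693545 to 115896320 in the positions of the file, whose genome build is not given in the sources used here. A count of Meis2 does not separate reads of an introduced sequence from those of the endogenous gene. No near-identical copy of Meis2 was found among the annotated transcripts. With each library's trend on gene length and GC content removed, a step added after the data were seen, the log2 fold change was 3.62 (SE 0.33) with an adjusted p of 0.0995, still the lowest p of all genes tested.

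Meis2 was the only gene past an adjusted p of 0.05 in edgeR's test, so 1 gene was higher and 0 were lower. At an unadjusted p under 0.05, 1253 genes were higher and 53 lower, where 640 in all would be expected by chance. DESeq2, with its default filter setting, called 61 genes higher and 1 lower, and limma-voom called 1 gene. With that filter set for the threshold of 0.05, DESeq2 called 74 genes. The biological coefficient of variation was 27.95%, the median SE of a log2 fold change was 0.376, and 7.5% of 2-fold changes were recovered in simulated libraries of this spread, so most 2-fold changes of single genes would go uncalled here. The count rose when either MEIS2 library was left out. The spread in such a fit comes from the controls alone, on fewer residual degrees of freedom than the 2 of the main fit. Its count of called genes is therefore not comparable with that of the main fit.

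Next to Meis2, the lowest p-value belonged to Sumo2, which encodes a small ubiquitin-like protein that is attached to other proteins. Sumo2 (chromosome 11, 115413928 to 115427102) measured 5.39 ± 1.26 CPM in the controls and 36.2 ± 18.9 CPM in the MEIS2 libraries, a log2 fold change of 2.75 (SE 0.45) with an adjusted p of 0.168. It has 14 near-identical copies in the table, 6 of them with counts, and the log2 fold change of Sumo2 and its copies together was 0.48. Col12a1, a collagen chain, had a log2 fold change of 1.63 (SE 0.34), Crebbp, a histone acetyltransferase, 2.02 (SE 0.42), and Ago2, an Argonaute protein of RNA interference, 1.55 (SE 0.33), each with an adjusted p of 0.256. These 3 genes are 15228, 13540 and 14031 bases long, against a median of 4219 over the tested genes, and their log2 fold changes were 0.75, 1.34 and 0.77 with the length and GC trend removed. On the other side, Rpl21, a protein of the large ribosomal subunit (chromosome 5, 146769700 to 146773842), measured 110.4 ± 1.27 CPM in the controls and 43.7 ± 1.22 CPM in the MEIS2 libraries. Its log2 fold change was -1.34 (SE 0.31) with an adjusted p of 0.256, and -1.33 with the trend removed. Rpl21 has 84 near-identical copies in the table, 40 of them with counts, and the log2 fold change of gene and copies together was -0.70. Adam11 had a log2 fold change of -2.31 (SE 0.72, adjusted p 0.279) from 33 and 16 counts against 4 and 6. Coa4, a mitochondrial protein, stood at -1.16 (SE 0.42, adjusted p 0.313). Sod3, the extracellular superoxide dismutase, stood at -0.99 (SE 0.36, adjusted p 0.316), with 35.2 ± 4.87 against 17.7 ± 2.30 CPM. Ifitm6 stood at -1.73 (SE 0.64, adjusted p 0.341) from 30 and 22 counts against 6 and 10.

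**Figure D1:**
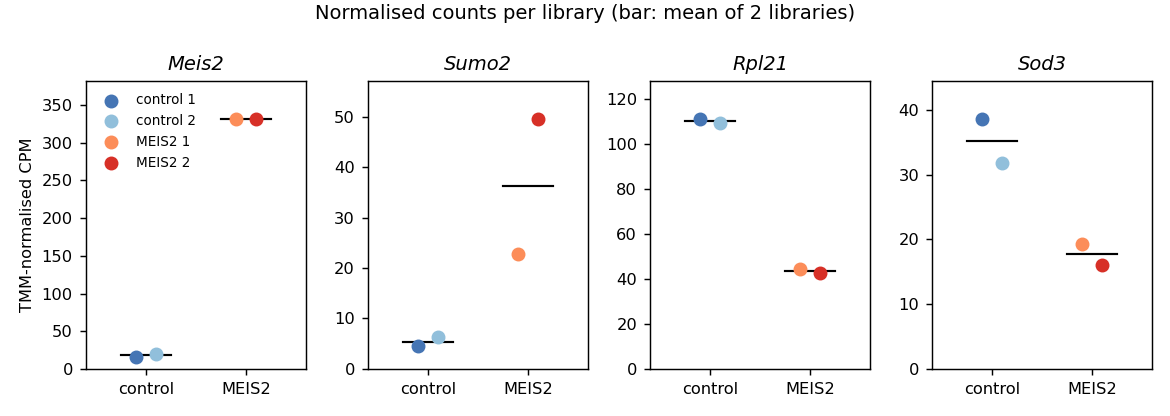
TMM-normalised CPM (vertical axis) of Meis2, Sumo2, Rpl21 and Sod3 in each library, with control libraries in blue, MEIS2 libraries in orange and red and a bar at the mean of the 2 libraries of a line. Meis2 is at 16 and 19.6 CPM in the controls and at 332.0 and 332.1 CPM in the MEIS2 libraries, while the MEIS2 libraries differ from each other in Sumo2, at 22.8 and 49.6 CPM.

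The libraries of 1 line differed from each other as well as from the other line. The first principal component held 74.2% of the variance and placed control replicate 1 at -47.8, control replicate 2 at -9.4, MEIS2 replicate 1 at -9.5 and MEIS2 replicate 2 at 66.7. The median absolute deviation over genes of log2 differences, scaled by R's default to estimate an SD, was 0.477 between the controls. It was 0.777 between the MEIS2 libraries and 0.338 between MEIS2 replicate 1 and control replicate 2. Across genes, which are not independent replicates, the difference between the lines was higher for longer genes (Spearman rho 0.488) and lower for genes of higher GC content (rho -0.421). The same held within a line: replicate 2 minus replicate 1 had a rho with length of 0.317 in the controls and 0.429 in the MEIS2 line, and with GC content of -0.532 and -0.64. For MEIS2 replicate 1 minus control replicate 2, rho was 0.093 with length and 0.375 with GC content. In the longest bin of genes, with a median of 12258 bases, MEIS2 replicate 2 stood 0.72 above the gene mean on the log2 scale and control replicate 1 stood at -0.53.

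**Figure D2:**
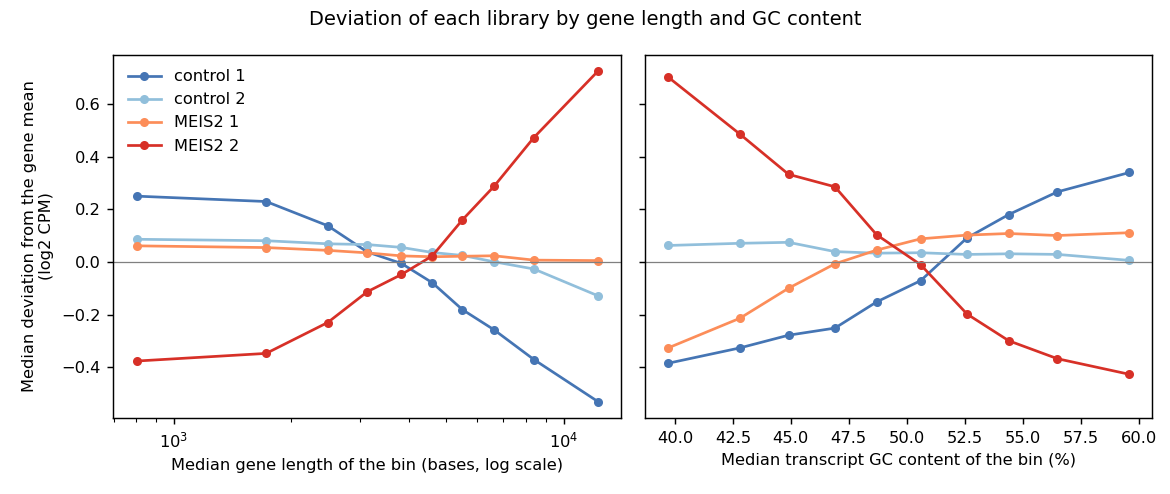
Median deviation of each library from the gene mean (vertical axis, log2 CPM) in 10 bins of gene length in bases (left, log scale) and of transcript GC content in percent (right), 1 line per library. Control replicate 1 and MEIS2 replicate 2 slope in opposite directions, from 0.25 and -0.38 in the shortest genes to -0.53 and 0.72 in the longest.

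Genes of protein synthesis and respiration ranked lower than other genes in the MEIS2 line. Of 70 tested cytosolic ribosomal protein genes, 69 had a lower fitted level, with a median log2 fold change of -0.47 (quartiles -0.56 and -0.42) and an adjusted p of 2.25e-14 by camera with the preset correlation, or 0.584 with an estimated correlation. Of 46 nuclear genes of oxidative phosphorylation, 43 were lower, with a median of -0.49 and an adjusted p of 8.46e-11, or 0.584 with an estimated correlation. Rpl21 was not on the ribosomal list. In both lists 0 members passed over all genes or adjusted over the list alone. The lowest p-values, chosen after the values were seen, were those of Rpl38 (log2 fold change -0.61, SE 0.33), Rpl18 (-0.64, SE 0.35) and Rpl12 (-0.59, SE 0.33), and of Ndufb3 (-0.68, SE 0.34), Ndufs7 (-0.66, SE 0.34) and Atp5o (-0.68, SE 0.35). In that order, they stood at -0.14, -0.59, -0.55, -0.57, -0.24 and -0.59 with the trend removed. Without control replicate 1, Rpl38 stood at -0.31, Ndufs7 at -0.32 and Atp5o at -0.41, and without MEIS2 replicate 2 Rpl18 stood at -0.40 and Atp5o at -0.37. Without MEIS2 replicate 1, Rpl38, Rpl18, Ndufs7 and Atp5o stood at -0.93, -1.01, -1.01 and -1.17. The median deviation of the ribosomal list was 0.43 and 0.09 in control replicates 1 and 2, and 0.07 and -0.60 in MEIS2 replicates 1 and 2. That of the oxidative phosphorylation list was 0.43, 0.11, 0.05 and -0.60. The ribosomal median was -0.31 without control replicate 1, -0.92 without MEIS2 replicate 1 and -0.26 without MEIS2 replicate 2, and the oxidative phosphorylation median was -0.31, -0.89 and -0.27. Both lists kept their calls with the trend removed (medians -0.27 and -0.37, adjusted p 1.71e-05 and 9.26e-06), or an adjusted p of 0.647 each with an estimated correlation.

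Smaller shifts to lower levels were called for lysosome and autophagy genes and for DNA replication genes. Of 37 lysosome and autophagy genes, 28 were lower, with a median log2 fold change of -0.30 and an adjusted p of 0.00885 by camera, or 0.584 with an estimated correlation. Examples chosen after the values were seen are Mcoln1, a lysosomal calcium channel (-0.56, SE 0.31), Gabarap, which binds autophagosome membranes (-0.61, SE 0.35), and Ctsa, a lysosomal protease (-0.53, SE 0.32). Of 31 genes of DNA replication and the G1/S transition, 23 were lower, with a median of -0.22 and an adjusted p of 0.0185, or 0.584 with an estimated correlation. They include Chaf1b, a subunit of a histone chaperone (-0.59, SE 0.32), Rfc3, of the clamp loader (-0.49, SE 0.31), and Gins2, of the replicative helicase (-0.47, SE 0.31). Without control replicate 1 Mcoln1 stood at -0.36 and Gabarap at -0.40, and Gabarap, Ctsa and Chaf1b stood at -0.31, -0.34 and -0.39 without MEIS2 replicate 2. Without MEIS2 replicate 1, Gabarap, Ctsa, Chaf1b and Gins2 stood at -1.08, -0.83, -0.90 and -0.71, and with the trend removed Mcoln1 stood at -0.91. In neither list did a member pass adjusted over the list alone. The lysosomal call was lost without MEIS2 replicate 2 (median -0.16, adjusted p 0.199), and the median was -0.20 without control replicate 1 and -0.50 without MEIS2 replicate 1. The DNA replication call was lost without control replicate 2 (median -0.13, adjusted p 0.0724) and without MEIS2 replicate 1 (median -0.30, adjusted p 0.0574). With scaling by library size alone, which moves the median of all tested genes from 0.01 to 0.17, the DNA replication median was -0.07 and its call stood.

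Genes of the extracellular matrix ranked higher in the MEIS2 line. Of 30 tested genes for collagens and matrix proteins, 23 were higher, with a median log2 fold change of 0.65 and an adjusted p of 2.16e-05 by camera, or 0.584 with an estimated correlation. Adjusted over the list alone, 8 members passed and all were higher, against 0 over all genes tested. They were the collagen chains Col3a1 (log2 fold change 0.95, SE 0.31), Col8a1 (1.64, SE 0.41), Col11a1 (1.88, SE 0.60) and Col12a1 (1.63, SE 0.34), the microfibril protein Fbn1 (1.37, SE 0.36), the crosslinking enzyme Lox (1.19, SE 0.36), Thbs1 (1.1, SE 0.35) and the proteoglycan Vcan (1.54, SE 0.46). Without MEIS2 replicate 2, Col8a1 stood at 0.78, Col11a1 at 1.12, Lox at 0.52, Thbs1 at 0.71 and Vcan at 0.50, and with the length and GC trend removed the 8 members ranged from 0.54 for Col3a1 to 1.11 for Col8a1. Col1a1, the most abundant marker on the fibroblast list, had a log2 fold change of 0.09 (SE 0.31), which was -0.03 without control replicate 2 and -0.14 without MEIS2 replicate 2. The list's median deviation was -0.36 and -0.18 in the controls and 0.07 and 0.44 in the MEIS2 libraries. Its median was 0.41 without MEIS2 replicate 2, and 0.30 with the trend removed, where the adjusted p was 0.000801, or 0.647 with an estimated correlation. Of 24 tested integrins and matrix proteases, 18 were higher (median 0.36, adjusted p 0.0588, with a median of 0.15 without MEIS2 replicate 2), and Itgav, an integrin chain, passed adjusted over the list alone (adjusted p 0.0403), with a log2 fold change of 1.51 that was 0.81 without MEIS2 replicate 2 or with the trend removed. With the trend removed, the integrin and protease list passed (median 0.20, adjusted p 0.0466, or 0.647 with an estimated correlation).

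The lists for 5 pathways ranked higher as well, while the retinoic acid, NF-kB and MAPK feedback lists were not called with the 4 libraries as counted. Of 27 tested genes of the TGF-beta and BMP pathway, 25 were higher, with a median log2 fold change of 0.67 and an adjusted p of 0.00012 by camera, or 0.584 with an estimated correlation. They include the receptors Bmpr2 (1.90, SE 0.53) and Tgfbr3 (1.16, SE 0.37) and Smad7, an inhibitor of the pathway (1.32, SE 0.41), which were chosen after the values were seen, and 0 members passed adjusted over the list alone. Bmpr2 rested on MEIS2 replicate 2, with 12.6 and 15.8 CPM in the controls against 19.6 and 86.3 CPM, and stood at 0.43 without that library, where Tgfbr3 stood at 0.75, and at 0.74 with the trend removed. In the Notch pathway, 11 of 14 were higher (median 0.66, adjusted p 0.00925, or 0.584 with an estimated correlation), and the receptor Notch2 passed adjusted over the list alone with 53.1 ± 1.08 against 129.7 ± 20.2 CPM. In the Wnt pathway, 17 of 23 were higher (median 0.42, adjusted p 0.00419, or 0.584 with an estimated correlation), and 4 passed adjusted over the list alone. These were the receptors Fzd5 (1.73, SE 0.44) and Fzd7 (1.25, SE 0.34), the co-receptor Lrp6 (1.5, SE 0.42) and Znrf3 (1.55, SE 0.44), a ligase that removes Frizzled receptors. Lrp6 stood at 0.72 without MEIS2 replicate 2 and at 0.63 with the trend removed. In axon guidance, 21 of 30 were higher (median 0.49, adjusted p 0.00222, or 0.584 with an estimated correlation), and Sema5a, Nrp2, Unc5c and Efnb2 passed adjusted over the list alone, with log2 fold changes of 1.32, 1.03, 1.33 and 1.26. With the trend removed these were 0.28, 0.43, 0.29 and 0.97, and without MEIS2 replicate 2 they were 0.62, 0.71, 0.68 and 0.81. Of 24 genes listed for the Hippo pathway, 20 were higher (median 0.32, adjusted p 0.00815, or 0.584 with an estimated correlation), and Tead1, the DNA-binding partner of YAP, passed adjusted over the list alone (log2 fold change 1.78, SE 0.40, or 1.05 without MEIS2 replicate 2 and 0.93 with the trend removed).

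Several of these pathway calls changed with the libraries used. Leaving out control replicate 2 ended the calls of the Wnt, Notch and Hippo lists (adjusted p 0.135, 0.0892 and 0.0688), and leaving out MEIS2 replicate 1 ended those of the Notch and Hippo lists (0.13 and 0.0574). Without MEIS2 replicate 2, the TGF-beta and BMP median was 0.28 and the Notch median 0.38, and without MEIS2 replicate 1 the Wnt median was 0.79. The pathway lists kept their calls with the trend removed, at medians of 0.50 for TGF-beta and BMP, 0.30 for Notch, 0.25 for Wnt, 0.23 for axon guidance and 0.35 for Hippo, and the adjusted p of each was then 0.647 with an estimated correlation.

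Messenger RNAs of the mitochondrial genome, listed as a sign of RNA quality, were higher for 10 of 12 genes, with a median log2 fold change of 0.63 and an adjusted p of 0.0163 by camera, or 0.6 with an estimated correlation. These mRNAs encode subunits of the same respiratory complexes whose nuclear genes ranked lower. The lowest p-values, chosen after the values were seen, were those of mt-Nd5 (1.12, SE 0.36), mt-Nd4 (1.03, SE 0.35) and mt-Nd6 (0.82, SE 0.31), which stood at 0.69, 0.59 and 0.49 without MEIS2 replicate 2. The mitochondrial mRNAs together held 0.655% and 0.909% of all counts in the controls and 0.918% and 1.27% in the MEIS2 libraries. The call was lost without control replicate 1 (median 0.28, adjusted p 0.186) and without MEIS2 replicate 2 (median 0.14, adjusted p 0.48), and the median was 1.00 without MEIS2 replicate 1. The call stood with the trend removed, at a median of 0.37 (adjusted p 0.0193, or 0.647 with an estimated correlation), and mt-Nd6 stood at 0.52. An annotated 18S ribosomal RNA gene held 0.777%, 0.853%, 0.783% and 1.2% of counts in control replicates 1 and 2 and MEIS2 replicates 1 and 2. Of 7 tested genes on the list of replication-dependent histones, 7 were lower (median -0.19, adjusted p 0.284 by camera), with a median of -0.48 without MEIS2 replicate 1 and -0.07 with the trend removed. The list was meant for mRNAs without a poly(A) tail, but whether these 7 lacked one was not tested.

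**Figure D3:**
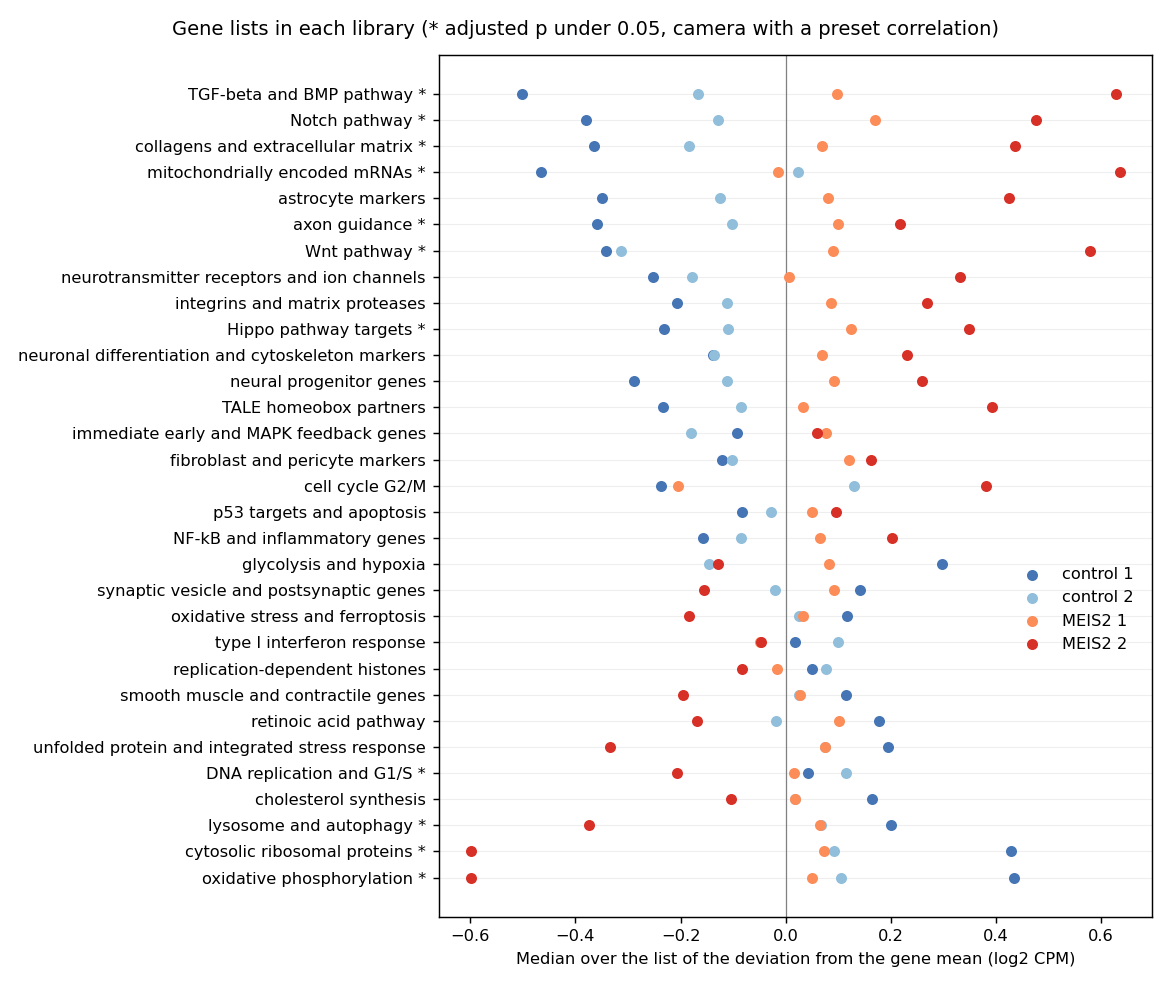
Median deviation from the gene mean (horizontal axis, log2 CPM) of the 31 tested lists in each of the 4 libraries, with control libraries in blue and MEIS2 libraries in orange and red and an asterisk at lists called by camera with the preset correlation. Control replicate 1 and MEIS2 replicate 2 lie at opposite ends of the ribosomal list, at 0.43 and -0.60, and the other 2 libraries lie between them, at 0.09 and 0.07.

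The lists of other TALE genes and of HOX genes had no member past the threshold. The list named for TALE homeobox partners leaves out Meis2 and includes Pbxip1 and TALE genes that are not binding partners, such as Meis1 and Meis3. Of its 13 tested genes, 10 were higher, with a median log2 fold change of 0.26 and an adjusted p of 0.178 by camera. The median was -0.03 with the trend removed and 0.64 without MEIS2 replicate 1. Among those chosen after their values were seen, Meis1 stood at 0.53 (SE 0.37), Pbx3 at 0.83 (SE 0.42) and Meis3 at -0.55 (SE 0.38). With the trend removed they stood at -0.033, 0.45 and -0.27, and without MEIS2 replicate 2 at 0.36, 0.39 and -0.31. Without MEIS2 replicate 1 they stood at 0.64, 1.13 and -0.91. Of 39 HOX genes, 28 had 0 counts in all libraries and 4 could be tested, too few for a list test. All 4 were higher, near the limit of detection, with log2 fold changes, among others, of 0.42 (SE 0.55) for Hoxa5, 1.04 (SE 0.53) for Hoxa6 and 0.88 (SE 0.64) for Hoxc4. The lowest adjusted p over the list alone was 0.288.

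Apart from axon guidance, no list of neuronal genes was called with the 4 libraries as counted. Of 27 neuronal differentiation markers, 17 had 0 counts in all 4 libraries, among them Gap43 and Mapt, and 6 could be tested, of which 3 were higher and 3 lower (median 0.30, adjusted p 0.365, with a median of 0.10 without MEIS2 replicate 2 and 0.07 with the trend removed). A count of 0 allows a level of up to 0.177 to 0.2 CPM. The neuronal tubulin Tubb3 stood at -0.40 (SE 0.39) and the microtubule protein Map2 at 0.93 (SE 0.45), or at -0.021 and -0.034 with the trend removed. Without MEIS2 replicate 2 they stood at -0.21 and 0.22, and Tubb3 ranged from -0.17 without control replicate 1 to -0.71 without MEIS2 replicate 1. Of 30 synaptic genes, 10 had 0 counts in all 4 libraries, as had 21 of 33 neurotransmitter receptors and ion channels. Synaptic genes had 5 of 12 higher (median -0.10, adjusted p 0.892), and receptors and channels had 5 of 6 higher (median 0.37, adjusted p 0.343). The receptor and channel median was 0.023 without MEIS2 replicate 2, 0.68 without MEIS2 replicate 1 and -0.044 with the trend removed. The synaptic median was 0.029 without control replicate 1 and -0.058 with the trend removed. It was -0.23 without control replicate 2 and -0.19 without MEIS2 replicate 1. Of 14 tested neural progenitor genes, 12 were higher (median 0.29, adjusted p 0.0969), and Notch2 passed adjusted over this list alone. The median was 0.12 without control replicate 1, 0.49 without control replicate 2 and 0.17 without MEIS2 replicate 2. The progenitor filament genes Nes and Vim stood at 0.77 (SE 0.34) and 0.16 (SE 0.34). Nes stood at 0.28 without MEIS2 replicate 2, and Vim at -0.0087 with the trend removed.

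Of 29 genes of the G2/M phases, 16 were higher and 13 lower, with a median log2 fold change of 0.15 and an adjusted p of 0.791. Mki67, Cenpe and Cenpf, markers of dividing cells, passed adjusted over the list alone (adjusted p 0.0435 each) and were set apart by MEIS2 replicate 2. Mki67 measured 40.3 and 53.8 CPM in the controls, 49.9 CPM in MEIS2 replicate 1 and 306 CPM in MEIS2 replicate 2, and its log2 fold change of 1.92 was 0.05 without that library. Without it, Cenpe and Cenpf stood at 0.29 and 0.33, against 2.03 and 2.38 with it. The list's median was -0.23 without MEIS2 replicate 2, -0.13 without control replicate 1 and -0.09 with the trend removed.

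Apart from the oxidative phosphorylation and lysosome lists above, stress, immune and metabolic lists did not pass with the 4 libraries as counted. Of those that did not pass, 2 passed with the length and GC trend removed. These were the immediate early and MAPK feedback genes (median 0.28, adjusted p 0.00116) and cholesterol synthesis (median -0.24, adjusted p 0.0485), each with an adjusted p of 0.647 with an estimated correlation. The unfolded protein and integrated stress response had 20 of 28 genes lower (median log2 fold change -0.22, adjusted p 0.0603), with a median of -0.48 without MEIS2 replicate 1, -0.09 without MEIS2 replicate 2 and near 0 with the trend removed. The type I interferon response had 23 of 36 lower (median -0.15, adjusted p 0.131). Isg15, an interferon-induced ubiquitin-like protein chosen after its value was seen, measured 1108 ± 39.1 against 755 ± 51.0 CPM, a log2 fold change of -0.55 (SE 0.32, adjusted p 0.578), or -0.18 with the trend removed. Cholesterol synthesis had 14 of 23 lower (median -0.22, adjusted p 0.178), oxidative stress and ferroptosis 16 of 29 lower (median -0.11, adjusted p 0.516), and p53 targets and apoptosis 17 of 27 higher (median 0.09, adjusted p 0.88). NF-kB and inflammatory genes had 13 of 23 higher (median 0.05, adjusted p 0.689), immediate early and MAPK feedback genes 18 of 28 higher (median 0.18, adjusted p 0.501), and glycolysis and hypoxia genes 16 of 32 higher (median 0.01, adjusted p 0.516). The retinoic acid pathway had 7 of 11 lower (median -0.22, adjusted p 0.729), and smooth muscle and contractile genes 11 of 18 lower (median -0.19, adjusted p 0.516). The medians of the p53 and glycolysis lists were -0.05 and -0.02 without MEIS2 replicate 2, and those of the oxidative stress and glycolysis lists were 0.05 and -0.10 with the trend removed. The glycolysis median was -0.21 without control replicate 2, and the oxidative stress median was -0.275 without MEIS2 replicate 1. The NF-kB median was 0.01 without control replicate 1, 0.22 without control replicate 2 and 0.25 without MEIS2 replicate 1. The interferon median was -0.07 without control replicate 2, the retinoic acid median was -0.10 without control replicate 1 and -0.08 without MEIS2 replicate 2, and the smooth muscle median was -0.34 without MEIS2 replicate 1. The mean was above 0 and the median below it for the synaptic, oxidative stress and retinoic acid lists, whose test pointed down, the mean was 0.00 for the smooth muscle list, and the test pointed down for the glycolysis list. With scaling by library size alone the synaptic, oxidative stress and interferon medians were 0.06, 0.04 and 0.02. With DESeq2 size factors the NF-kB and glycolysis medians were -0.01 and -0.05, and with upper quartile scaling the glycolysis median was -0.01.

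No marker of another cell type passed over all genes tested. Of 5 tested astrocyte markers, 4 were higher (median log2 fold change 0.50, adjusted p 0.436), and the most abundant, Gja1, stood at 0.50 (SE 0.34), or at 0.16 without MEIS2 replicate 2 and -0.069 with the trend removed. Of 8 fibroblast and pericyte markers, 6 were higher (median 0.15, adjusted p 0.236). The other lists had too few tested members for a list test. The oligodendrocyte lineage list had 3, of which Cspg4 was the most abundant at 151 ± 0.449 against 163 ± 16.2 CPM, a log2 fold change of 0.11 (SE 0.30) that was -0.0083 without MEIS2 replicate 1 and -0.14 with the trend removed, and Pdgfra measured 8.11 ± 1.06 against 17.5 ± 3.57 CPM, a log2 fold change of 1.1 (SE 0.40). The 3 tested microglia and macrophage markers were all lower (median -0.36, or -0.05 with the trend removed), and Tmem119 stood at -0.40 (SE 0.37), or -0.031 with the trend removed. Their median was -0.67 without MEIS2 replicate 1, and Tmem119 then stood at -0.68, against -0.15 without control replicate 1. The 2 tested endothelial markers were higher, and Flt1 stood at 1.53 (SE 0.54) from 1.88 ± 0.819 CPM in the controls. The 1 tested epithelial marker, Grhl2, stood at 2.24 (SE 0.76), from 6 and 2 counts against 18 and 22. Pdgfra, Flt1 and Grhl2 passed adjusted over their lists alone (adjusted p 0.0422, 0.0254 and 0.0102). Lists of 3, 2 and 1 tested members adjust for little. Over all genes in edgeR's test, Pdgfra, Flt1 and Grhl2 had an adjusted p of 0.314, 0.308 and 0.297. With the trend removed they stood at 0.52, 0.82 and 1.81, and Flt1 stood at 0.84 without MEIS2 replicate 2.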

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

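The offset for gene length and GC content was chosen after the data were seen. The log2 fold change of Meis2 kept its sign under each alternative, from 3.54 to 4.37, and its call under all but that offset, where it was 3.62 (adjusted p 0.0995): the SE hardly moved (0.34 and 0.33), while the prior degrees of freedom that edgeR adds to the 2 of the libraries went from 12.35 to 5.35. The count of called genes stayed at 1 under the other scalings, the stricter filter and threshold, limma-voom and the test against a 1.5-fold change. It was 271 with no filter on low counts, 62 with DESeq2 and 0 with the offset (1035 genes higher and 583 lower at an unadjusted p under 0.05), and ranged from 1 to 2411 when 1 library was left out, the highest without MEIS2 replicate 1. The lists called numbered 0 with an estimated correlation (lowest adjusted p 0.584) and 0 with fry in its directional and mixed tests (lowest 0.235 and 0.387). They numbered 12 with the replicate number as a block, 14 with the offset, 15 with both, and 11 with DESeq2 size factors or library size alone. The totals with the block or the offset hold all 11 main calls and lists called in addition. Without 1 library, some of the 11 calls were lost, as given above. The replicate number as a block gave 2795 genes (1883 higher, 912 lower), and 2547 together with the offset. The cause of these differences in count was not tested. Same-numbered libraries deviated together (correlation across genes 0.529, or 0.331 with the offset), but the labels do not say that the numbers are pairs and 2 pairs cannot show it.

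Of the other genes named here, these turned sign with the offset alone and with the offset and block: Gja1 (-0.069 and -0.081), Cspg4 (-0.14 and -0.14), Meis1 (-0.033 and -0.046), Vim (-0.0087 and -0.019) and Map2 (-0.034 and -0.034). Without 1 library, Cspg4 ranged from -0.0083 to 0.17, Col1a1 from -0.14 to 0.23 and Gapdh from -0.42 to 0.59. None of these genes was called in edgeR's test, and the cause was not tested. The alternatives meant for normalised values were not run, since the values are counts. Depth limits genes near 0.2 CPM, where 3 counts are the floor.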

Other observations

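Of the tests below, those on the length and GC trend, on MEIS2 itself, on the copies of Rpl21 and on the lower and the higher lists apart were chosen only after the result was seen.

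The 6 genes below are among the 61 that DESeq2 called higher; they were picked after their values were seen, belong to no list fixed beforehand and were not tested for enrichment. The histone methyltransferase Kmt2a measured 17.3 ± 4.32 CPM in the controls and 68.6 ± 37.8 CPM in the MEIS2 libraries (SD, n = 2 each), with a log2 fold change of 1.99 (SE 0.42). The log2 fold changes of its relatives Kmt2d and Ash1l were 1.61 (SE 0.36) and 2.07 (SE 0.48), and that of the acetyltransferase Ep300 was 1.59 (SE 0.36). The ubiquitin ligases Huwe1 and Rnf213 stood at 1.54 (SE 0.34) and 1.35 (SE 0.35). Each of these 6 genes had an adjusted p of 0.256 in edgeR's test. With the length and GC trend removed, Kmt2a stood at 1.12, Kmt2d at 1.02, Ash1l at 1.1, Ep300 at 0.84, Huwe1 at 0.42 and Rnf213 at 0.55. Without MEIS2 replicate 2, Kmt2a stood at 1.24, Ash1l at 0.98 and Ep300 at 0.98. The genes called by DESeq2 had a median length of 14537.5 bases, against 4219 over the tested genes. Gapdh, often used as a reference gene, was counted at 19.5 ± 6.96 and 22.0 ± 10.1 CPM. Its near-identical copies were not sought, so this counts the reads given to the gene and is no measure of its expression.

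Long genes and genes of low GC content were higher on the mean of the MEIS2 libraries, but in the pairing of MEIS2 replicate 1 with control replicate 2 low-GC genes were lower (Spearman rho with GC content 0.375). A length and GC trend that differs between libraries of 1 line is a candidate explanation: replicate 2 minus replicate 1 correlated with gene length in both lines, and the lower of these Spearman rho values was 0.317. An effect of MEIS2 itself and another difference between the lines both stay open. The lowest rho with gene length over the 4 pairings of a MEIS2 library with a control library was 0.093. That value was above 0 but below the length values within a line. The GC rho of 0.375 in that pairing runs against the pattern. It is smaller in size than the -0.532 and -0.64 within a line. What made the libraries of a line differ was not tested.

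Whether the length and GC trend is the whole cause of the shifts of the ribosomal, respiratory, matrix and signalling lists stays open. With the trend removed, all 11 lists stayed past the threshold in the same direction by camera with its preset correlation. That test takes the genes of a list as nearly independent. The correlation estimated before the trend was removed was 0.801 for the ribosomal, 0.52 for the oxidative phosphorylation and 0.865 for the mitochondrial list. Any shift left between libraries can keep the call of such a list, so the test cannot decide. With an estimated correlation, 0 lists were called before or after the trend was removed. The larger difference within a line was at least as large as the difference between the lines in 5 of the 11 lists, which were all 4 lower lists and 1 higher list, the mitochondrial mRNAs. With the trend removed it was so in 3 lists, the ribosomal, lysosomal and Wnt lists, so the division by direction did not hold. Spread between libraries of 1 line, an effect of MEIS2 and another difference between the lines all stay open for the lower and the higher lists. These lists were picked for their difference between the lines and were measured in the same 4 libraries. They did not pass fry (adjusted p from 0.262 to 0.41 over the 11 lists), which could call little with 2 residual degrees of freedom.

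Rpl21 was lower and Sumo2 higher in both MEIS2 libraries than in both controls. The summed copies of Rpl21 did not rise (log2 fold change -0.27), and the gene and its copies together stood at -0.70. This argues against a move of reads to the copies found as the whole cause. A move of part of the reads stays open, also on top of a shift like that of the ribosomal list (median -0.47). Copies outside the transcripts searched were not sought, and the treatment of reads that match several genes is not given. Rpl21 itself held 48.3% and 50.6% of the counts of gene and copies in the controls and 30.4% and 33.3% in the MEIS2 libraries. For Sumo2 such a move stays open: Sumo2 and its copies together had a log2 fold change of 0.48, while the copies alone stood at -1.34. Sumo2 itself held 13.5% and 17.7% of these counts in the controls and 56.9% and 86.8% in the MEIS2 libraries. An effect of MEIS2 on either gene was tested neither apart from these copies nor apart from another difference between the lines.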
